A study of Arabidopsis thaliana with 6 samples.

How the data were processed

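The series holds RNA sequencing of cells sorted by fluorescence from root meristems of 6-day-old seedlings, with 6 libraries in 5 cell types. Per the labels' protocols, sorted cells were collected in lysis buffer, RNA was extracted with an RNeasy Plant kit or Trizol, and polyA+ libraries were built with the Illumina TruSeq RNA kit. The deposited values are FPKM, fragments scaled to transcript length and to the fragments mapped in the library, with 1 file per library and 33554 loci in each. Per the submitters' processing notes, TopHat 1.3.1, Bowtie 0.12.7, Cufflinks 2.0.2 and the build TAIR10 were used, without roles or settings. The annotation, strandedness, filters and treatment of reads that map to several places are not given in the sources used here. Near-identical copies, such as histone H3 and H4 genes and transposable elements, and overlapping genes are therefore uncertain. Libraries were grouped by the cell type in the labels. Only endodermis has 2 libraries, from reporter lines 1 and 2, and the labels do not say whether other differences in culture or day separate them, so the spread between them may be technical or biological. No batch, day or run is labelled.

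Locus identifiers were matched to a RefSeq table of the assembly TAIR10.1 for names, biotypes and products, and 32807 of 33554 identifiers matched. As the build name differs from that of the authors, no coordinates are printed. Where the reference gives another symbol for an identifier of a gene list, the symbol of the list is printed. Reads per library are not given in the sources used here. From loci under 0.5 FPKM in both libraries, the value of a single read relative to endodermis line 1 was estimated at 1.05-fold in epidermis, 1.58-fold in cortex, 1.21-fold in endodermis line 2, 0.97-fold in stele and 1.24-fold in columella root cap, where a larger value means a shallower library. This relative depth is a rough estimate, and FPKM give no interval for a single value. An exact 0 can be a failed estimate.

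Values were compared on the log2(FPKM + 1) scale, which understates differences of low genes. A gene was measured with 1 FPKM or more in at least 1 library, which left 19671. Enriched and depleted genes followed a rule of size with no p-value, as 4 of the 5 cell types have 1 library: a log2 margin of at least 1 outside every library of the other cell types, and 5 FPKM on the higher side. Both endodermis lines had to pass. As a secondary test, limma (eBayes with trend, 1 residual degree of freedom from the endodermis pair) compared each cell type with the mean of the other 4, with Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05 and a log2 difference of at least 1. It assumes that lone libraries vary like the endodermis pair, and its p-values measure only that spread. Its prior degrees of freedom, which set how far each gene is drawn to a spread shared across genes, were infinite in the main fit. The main p-values thus rest wholly on the shared spread. The prior was 3.50 with size factors, 9.15 without the trend and 1.22 with no filter on low values. Lower call counts in those settings go with this lower prior, and an effect of scaling alone was not tested. Gene lists (27 lists, 260 entries and 253 genes, set before the data were examined) were described by the median difference of their measured members and its percentile among 10000 random lists of equal size matched on expression in 20 bins. A percentile describes these libraries and is not a p-value. Reference classes do not name transposable element genes, so the biotype pseudogene was used in their place.

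Named genes were drawn by a rule set before the data were examined. The rule takes, per cell type, the 10 largest margins above and the 5 largest below, list members that were enriched or depleted (at most 8 per list), the reporter genes, a fixed set of methylation and chromatin genes, and the 5 largest differences in each direction between the endodermis lines. Other list members appear as examples chosen after their values were seen. Not all genes that meet the rule are reported here, and which of them to report was also decided after their values were seen. Alternatives covered the pseudocount, the FPKM minimum, the fold, size factors, TPM, quantile normalization, averaging of the endodermis lines, leaving out each line, and limma settings. Alternatives without the epidermis or the columella root cap library were chosen after seeing the data, as were all alternatives for list medians outside the columella root cap. The computations were tested on simulated libraries of 19671 genes with 200 genes changed in columella root cap and noise as wide as the endodermis pair. The rule of size recovered 12% of genes changed 2-fold, 50% at 4-fold, 78% at 8-fold and 84% at 16-fold, and limma 0%, 2%, 22% and 46%, with 3 of its 38 calls on unchanged genes. A simulated list changed 4-fold stood at the 100 percentile of random lists and an unchanged list at 38.1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1 were used.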

Results

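Gene expression was measured by RNA sequencing in cells sorted by fluorescence from the root meristem of 6-day-old Arabidopsis thaliana seedlings. Each library came from a reporter line whose green fluorescent protein marks a cell layer. Epidermis was sorted with the WER promoter, cortex with the AT1G09750 promoter, endodermis with the SCR promoter, stele (the central vascular cylinder) with the WOL promoter and columella root cap with the enhancer trap PET111. The 6 libraries covered 5 cell types, with 2 endodermis libraries (line 1 and line 2) and 1 library for each of the other 4 cell types. Each library listed FPKM for 33554 loci, with between 15999 and 17096 of them at 1 FPKM or more, and the summed FPKM lay between 576322 and 642028. The number of reads behind each library was not given in the sources used here, so no counting interval could be set on a value. Apart from endodermis, every value below comes from a single library and has no replicate check.

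The genes behind the sorting reporters were examined first. WER (AT5G14750), a MYB regulator of epidermal cell fate, was at 91.3 FPKM in epidermis and at most 12.8 elsewhere. AED3 (AT1G09750), the gene of the cortex reporter, was at 43.0 FPKM in cortex and at most 5.51 in the other libraries. SCR (AT3G54220), a GRAS regulator of endodermis and ground tissue, was at 59.7 and 147 FPKM in endodermis lines 1 and 2, a mean of 103 ± 61.9 (SD, n = 2), against 36.5 in cortex and at most 14.7 elsewhere. WOL (AT2G01830), a cytokinin receptor kinase, was highest in stele at 46.0 FPKM, but its 30.7 FPKM in epidermis left a margin of under 2-fold. The label of each of these libraries thus matched the library with the highest value of its reporter gene, and no single gene stands for PET111.

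A gene was called enriched in a cell type when it stood at least 2-fold above every library of the other cell types with at least 5 FPKM, and depleted when it stood at least 2-fold below all of them. Columella root cap had 1071 enriched and 218 depleted genes, epidermis 878 and 190, stele 305 and 433, cortex 162 and 9, and endodermis, where both lines had to pass, 134 and 0. Noise as wide as the difference between the 2 endodermis lines, simulated on unchanged genes, gave 410 enriched and 289 depleted genes for the columella root cap, 379 and 263 for epidermis, 365 and 238 for stele, 408 and 245 for cortex, and 56 and 37 for endodermis. Enriched counts exceeded that simulation in columella root cap, epidermis and endodermis, and depleted counts in stele. The enriched counts of stele and cortex, and the depleted counts of the other 4 cell types, lay below it. The simulated noise is wide, as the endodermis lines differed at 43.0% of genes compared. Cortex and endodermis line 2 differed at only 11.6%, and line 2 and stele at 17.0%. A count below the simulation therefore does not show that its genes are noise.

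**Figure D1:**
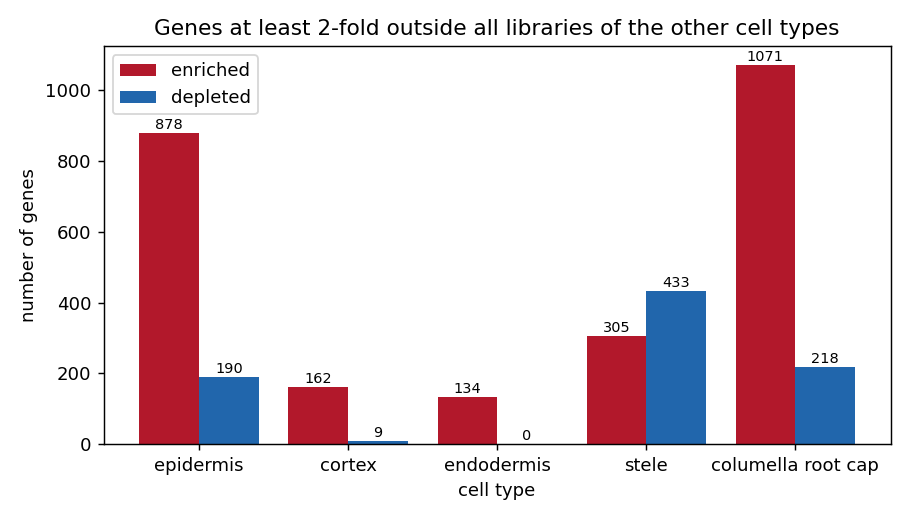
Number of genes (vertical axis) at least 2-fold above (red) or below (blue) all libraries of the other cell types, per cell type (horizontal axis). Columella root cap has the most enriched genes, 1071, and stele the most depleted, 433.

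The first comparison asked what sets the columella root cap, the gravity-sensing tip of the root, apart from the other 4 cell types. Its largest margins included RGF2 (AT1G13620) and RGF3 (AT2G04025), which encode root meristem growth factor peptides, at 1377 and 1944 FPKM against at most 8.62 and 26.9 in any other library. ADF9 (AT4G34970), an actin depolymerizing factor, was at 1258 FPKM against at most 10.7. LZY2 (AT1G17400), of the LAZY family that acts in gravity signalling, was at 151 FPKM against at most 1.01. GBSS1 (AT1G32900), which makes the amylose of starch granules, was at 153 FPKM against at most 2.08. The remaining genes among the 10 largest margins were AT3G60650, AT1G72490, AT3G60647, AT3G48450 and AT3G55550, at 165, 336, 127, 89.1 and 51.3 FPKM. AT3G60650 and AT3G60647 have neighbouring identifiers, and whether reads were shared between them was not given in the sources used here.

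Root cap markers stood together in this library. Their median difference from the other 4 cell types was 3.65 on the log2(FPKM + 1) scale. Of 10 markers 8 lay above the range of all other libraries with a difference of at least 1. SMB (AT1G79580) and FEZ (AT1G26870), NAC transcription factors of the root cap, were at 98.2 and 87.2 FPKM in columella root cap against at most 32.4 and 9.61 elsewhere, in both cases in epidermis. COBL2 (AT3G29810) was at 26.7 and ARF10 (AT2G28350), an auxin response factor, at 42.4 FPKM. Of the 6 genes of root cap cell death, whose median was 2.71, only SCPL48 (AT3G45010) was enriched, at 235 against at most 81.8 FPKM.

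Starch genes were also high in the columella root cap. In the synthesis list 12 of 13 members were higher than the mean of the other cell types and 5 were enriched (median 1.69), among them ADG1 (AT5G48300), the small subunit of ADP-glucose pyrophosphorylase, at 138 against at most 41.3 FPKM, PGM1 (AT5G51820) at 53.9 against 15.5, and SBE2.2 (AT5G03650) at 54.5 against 11.4. In the breakdown list all 8 measured members were higher and 6 were enriched (median 3.05). GWD1 (AT1G10760), which phosphorylates starch, was at 165 FPKM against at most 11.6, ISA3 (AT4G09020), a debranching enzyme, at 150.0 against 19.0, and MEX1 (AT5G17520), the maltose exporter, at 68.6 against 11.9. Auxin transporters (median 1.84) included the efflux carriers PIN4 (AT2G01420) at 547 and PIN3 (AT1G70940) at 171 FPKM, against at most 86.6 and 78.6. The stem cell niche regulators PLT1 (AT3G20840) and PLT2 (AT1G51190) were at 79.6 and 43.6 FPKM against at most 15.7 and 10.6. Medians of the root cap marker, starch synthesis, starch breakdown, auxin transport and stem cell niche lists lay at or above the 99.97 percentile of random lists matched on expression. In limma 8 of the 10 root cap markers were called over all genes and 10 adjusted over the list alone, with 2 and 4 for starch synthesis, 4 and 6 for starch breakdown, 3 and 4 for auxin transport, 1 and 3 for the stem cell niche, and 2 and 5 for root cap cell death.

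The series concerns DNA methylation, so genes of that machinery were examined in the columella root cap. Of 28 measured genes of RNA-directed DNA methylation, in which small RNAs guide new methylation, 4 were enriched. Over all 19671 measured genes 1071 were enriched in this library, or 8.66% of those at 5 FPKM or more in it. NRPD1 (AT1G63020), the largest subunit of RNA polymerase IV, was at 14.1 FPKM against at most 0.753, and CLSY1 (AT3G42670), a chromatin remodeller that acts with this polymerase, at 24.3 against 2.82. RDR2 (AT4G11130), which copies its transcripts into double strands, was at 18.7 against 6.00, and IDN2 (AT3G48670) at 53.6 against 19.3 FPKM. Further members were not enriched: DCL3 (AT3G43920) was at 4.51 FPKM against at most 2.41, CLSY2 (AT5G20420) at 1.99 against 0.0519, DRM2 (AT5G14620) at 10.5 against 9.57, NRPE1 (AT2G40030) at 4.53 against 6.12 in stele, and AGO4 (AT2G27040) at 22.2 against 60.1 in stele. CLSY3 (AT1G05490) and CLSY4 (AT3G24340) were at 0.0516 and 0.238 FPKM. The list median was 0.37, at the 94.0 percentile of random lists and inside their central 95% interval (-0.35 to 0.46), and 0.095 without the epidermis library. Above the range of all other libraries, with a log2 difference of at least 1 from the mean of the other cell types, lay 7 members. DRM2 also lay above that range, but its difference was 0.64.

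None of the maintenance genes was enriched. MET1 (AT5G49160), which copies CG methylation at replication, was at 5.09 FPKM in columella root cap against 5.92 to 36.9 in the other libraries, and CMT3 (AT1G69770), a methyltransferase for CHG sites, at 5.56 against 10.3 to 53.1. CMT2 (AT4G19020) was at 4.36 and DDM1 (AT5G66750), a remodeller of heterochromatin, at 8.46 FPKM, both inside the range of the others. The median of the 9 measured maintenance genes was -0.28 (16.7 percentile), also inside its interval (-0.67 to 0.85). Among 13 heterochromatin and chromatin assembly genes the median was -0.78 (1.65 percentile), with HTA6 (AT5G59870) and HTA7 (AT5G27670), histone H2A variants of heterochromatin, at 47.3 and 73.1 FPKM against at least 91.7 and 104 elsewhere, and the linker histones H1.1 (AT1G06760) and H1.2 (AT2G30620) at 36.5 and 36.3 against at least 57.1 and 54.9. HTA12 (AT5G02560) was at 7.77 FPKM, inside the range of the others. None of these 13 genes was depleted under the 2-fold rule. Among 9 measured demethylation genes the median was 0.18, with MBD7 (AT5G59800), a methyl-CpG-binding protein, enriched at 31.3 against at most 14.2 FPKM, and the DNA glycosylases ROS1 (AT2G36490) and DME (AT5G04560) at 8.14 and 11.0 FPKM, inside the range of the others. In limma, with Benjamini-Hochberg adjustment, the RNA-directed DNA methylation genes NRPD1, CLSY1 and CLSY2 were called over all genes, while the enriched RDR2 and IDN2 were not (adjusted p = 0.106 and 0.199), and 4 genes of the list were called when adjusted over it alone. The maintenance, demethylation and heterochromatin lists had 0 calls either way, with 1, 1 and 0 genes at an unadjusted p under 0.05.

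**Figure D2:**
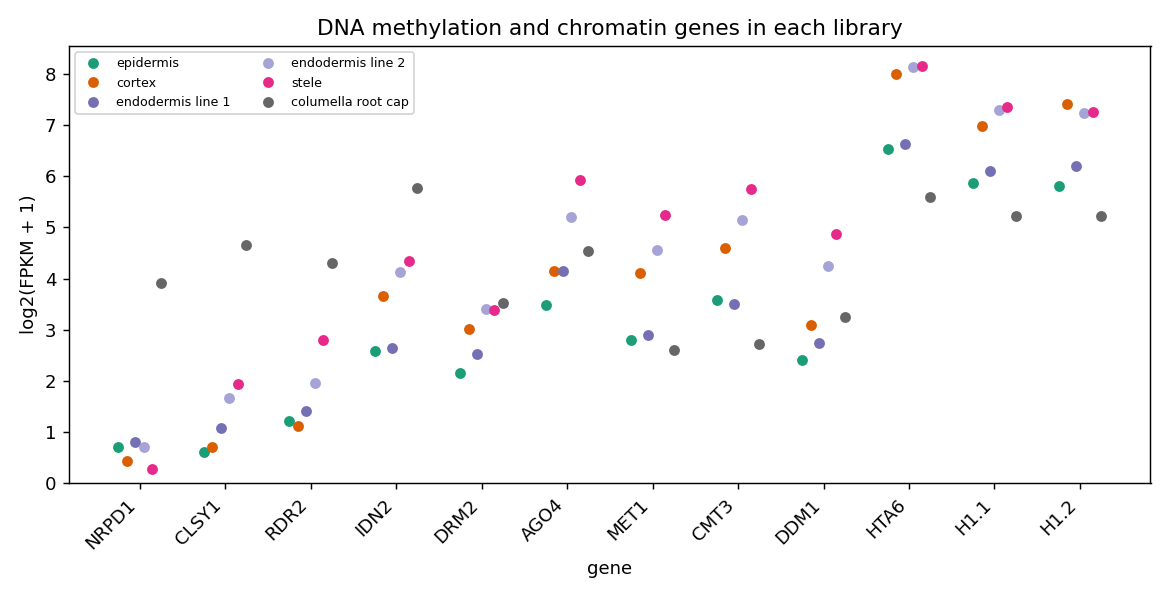
Expression in log2(FPKM + 1) (vertical axis) of 12 DNA methylation and chromatin genes (horizontal axis), 1 point per library, 6 libraries in colours. NRPD1, CLSY1, RDR2 and IDN2 have their highest point in columella root cap, and MET1, CMT3, HTA6, H1.1 and H1.2 their lowest.

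Cell cycle and replication genes were low beside these. All 12 genes of G2 and M phase lay below the range of the other libraries (median -1.63), with CDKB1;1 (AT3G54180) at 7.82 FPKM against at least 14.2 and KNOLLE (AT1G08560), the cytokinesis syntaxin, at 10.8 against at least 16.8. The S phase median was -0.87, although RNR2A (AT3G23580), a ribonucleotide reductase subunit, was enriched at 33.2 against at most 15.3 FPKM. The 5 replication-dependent histone H3 genes had a median of -1.96, the 8 histone H4 genes -1.63 and the 3 replacement H3 genes -0.45. The H4 gene AT5G59970 was depleted, at 15.8 against at least 37.9 FPKM. Histone copies are near identical in sequence, so the split of reads between them is uncertain. In limma the G2 and M phase list had 0 calls, with 0 genes at an unadjusted p under 0.05, and the S phase list 0, with 2. The 5 largest margins below the other libraries were those of TUB5 (AT1G20010), a beta-tubulin, at 6.95 against at least 67.5 FPKM, EXPA11 (AT1G20190), an expansin, at 2.42 against 26.6, BZIP61 (AT3G58120) at 6.53 against 59.3, SIM (AT5G04470), a kinase inhibitor of the cell cycle, at 3.34 against 29.4, and ARP1 (AT3G54770) at 5.13 against 40.0.

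2 further lists were high in the same library. Xylem markers had a median of 3.04, above the 1.59 of stele, and 5 of 8 were enriched, among them the peptidase gene XCP1 (AT4G35350) at 317 FPKM against 98.7 in stele and the secondary wall cellulose synthases CESA4 (AT5G44030), CESA7 (AT5G17420) and CESA8 (AT4G18780) at 77.3, 51.3 and 54.1 against 24.4, 21.0 and 15.3. Stele markers as a list had a median of -0.29. The stress and protoplasting list had a median of 1.59, with MPK3 (AT3G45640) at 356 FPKM against at most 74.2 and LOX3 (AT1G17420) at 119 against 19.2. All 6 libraries came from sorted cells, so handling of the cells cannot be told apart from a difference of cell type in this list. In the small RNA list outside this pathway (median 0.24), DCL4 (AT5G20320) and AGO2 (AT1G31280) were enriched, at 8.40 and 15.0 FPKM. In limma 6 of 8 xylem markers were called over all genes and 8 adjusted over the list alone, and 2 and 3 stress genes. Phloem, endodermis, cortex, epidermis and root hair markers had medians of -0.09, -1.52, -1.68, -0.71 and -1.90. The phloem median turned positive with TPM (0.16), at 5 FPKM (0.20), with no filter on low values (0.025) and with a pseudocount of 0.1 (0.017). Quantile normalization moved the median difference of all genes by -0.12 in this library. Without the epidermis library, tried after seeing the data, 1595 genes were enriched and 436 depleted in columella root cap, and the small RNA median was -0.074. In limma 992 genes were called (926 higher, 66 lower), and 0 when FPKM were divided by size factors, with 1895 genes then at an unadjusted p under 0.05.

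The second comparison set the epidermis against the other cell types. Root hair genes gave the clearest group. All 8 were enriched (median 5.61), with EXPA7 (AT1G12560), an expansin, at 196 against at most 4.18 FPKM, RSL4 (AT1G27740), a bHLH regulator of hair growth, at 71.6 against 1.52, and PRP3 (AT3G62680) at 436 against 15.5. Of 9 measured epidermis markers 4 were enriched (median 1.88): WER, GL2 (AT1G79840) at 11.7, RHD6 (AT1G66470) at 36.7 and MYB23 (AT5G40330) at 28.6 FPKM. The largest margins were those of BGLU35 (AT1G51470) and BGLU34 (AT1G47600), beta-glucosidases, at 146 and 131 FPKM against at most 1.56 and 1.69. The peroxidase gene AT5G17820 was at 736 against 17.4 and AIR1 (AT4G12550) at 576 against 14.5 FPKM.

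Among depleted genes of the epidermis were the auxin transporters LAX3 (AT1G77690), PIN7 (AT1G23080), LAX2 (AT2G21050) and PIN3, at 1.90, 1.19, 2.92 and 3.30 FPKM against at least 20.09, 10.5, 13.7 and 11.1. SUVH9 (AT4G13460), an RNA-directed DNA methylation factor, was depleted at 2.82 against at least 10.4 FPKM. That list had a median of -1.07, S phase -1.39 and stele markers -2.81. Root cap markers were mixed here: 6 of 10 were higher, with SMB at 32.4 and BRN1 (AT1G33280) at 47.8 FPKM, and 4 lower, among them the depleted PIN3 and PIN7, while none was enriched (median 1.02). Root cap cell death genes had a median of 2.1 and the stress list 0.95. In limma 8 root hair, 5 epidermis and 6 stele markers were called over all genes, and 8, 7 and 9 adjusted over the list alone. The RNA-directed and S phase lists had 0 calls either way, with 0 genes at an unadjusted p under 0.05 in both, and SUVH9 had an adjusted p of 0.448. Division by size factors moved the median difference of all genes by 0.37 in epidermis and the counts to 1177 enriched (93.2% of all called, from 82.2%) and 86 depleted. Leaving out endodermis line 1 gave 435 depleted genes, leaving out the columella root cap 1381 enriched and 407 depleted, and limma made 1311 calls as deposited and 0 with size factors, where 2261 genes had an unadjusted p under 0.05.

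The third comparison concerned the stele. CNA (AT1G52150), AHP6 (AT1G80100), TMO5 (AT3G25710) and SHR (AT4G37650), regulators of vascular patterning, were at 86.3, 27.7, 141 and 98.8 FPKM against at most 4.73, 1.5, 22.5 and 16.7, and 6 of 12 stele markers were enriched (median 3.64). The largest margins above included ACL5 (AT5G19530), a thermospermine synthase, at 194 against 10.4 FPKM, LOG3 (AT2G37210), which activates cytokinins, at 38.2 against 1.49, XND1 (AT5G64530), a xylem NAC factor, at 32.9 against 1.68, LAC6 (AT2G46570) at 52.0 against 2.99 and NAC105 (AT5G66300) at 47.0 against 3.06. AGO10 (AT5G43810), an Argonaute, was at 74.4 against 8.79 FPKM, and the phloem gene CVP2 (AT1G05470) at 16.9 against 2.63. Auxin carriers LAX2 and LAX3 were enriched at 270.0 and 286 FPKM, and PIN2 (AT5G57090) was depleted at 1.40 against at least 11.7.

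Dividing-cell and methylation genes were high in the same library, but not only there. Mean log2(FPKM + 1) of S phase, G2 and M phase, maintenance and heterochromatin lists was 5.62, 5.29, 4.25 and 4.71 in stele. It was 5.27, 4.74, 3.83 and 4.66 in endodermis line 2, and 3.78, 3.09, 2.46 and 3.78 in line 1. The endodermis lines were averaged for the medians below. For RNA-directed DNA methylation the mean was 3.04 in columella root cap against 3.06 in stele. The stele median of G2 and M phase was 2.08, with 11 of 12 above the range of the others at a log2 difference of at least 1. The stele medians of S phase, maintenance of methylation, RNA-directed DNA methylation and heterochromatin were 1.88, 1.28, 0.75 and 0.98. MET1 was at 36.9, CMT3 at 53.1, DDM1 at 28.3 and AGO4 at 60.1 FPKM, each the highest of the 6 libraries. Replication-dependent H3 and H4 genes had medians of 1.38 and 1.06. None of these genes was enriched. In limma these lists had 0 calls, over all genes or over the list alone, with 9 G2 and M phase, 4 S phase, 2 maintenance, 2 RNA-directed, 0 heterochromatin, 2 H3 and 0 H4 genes at an unadjusted p under 0.05. The demethylation median was 0.28, and turned to -0.020 with size factors. Stress genes went the other way (median -2.15): 5 of 11 were depleted, among them WRKY33 (AT2G38470) and WRKY40 (AT1G80840) at 3.89 and 13.1 FPKM against at least 11.96 and 42.3. The largest margins below were those of AT4G36640 at 0.574 FPKM, the methionine sulfoxide reductases MSRB7 (AT4G21830) and MSRB9 (AT4G21850) at 7.45 and 18.0, MDHAR (AT3G09940) at 2.39 and GLL22 (AT1G54000) at 3.07, against at least 39.5, 177, 305, 59.2 and 70.5. Size factors moved the median difference of all genes by -0.26 in stele. Without endodermis line 2 there were 1221 enriched and 685 depleted genes, and without the columella root cap 662 depleted. In limma 585 genes were called, and 0 with size factors, where 1790 had an unadjusted p under 0.05.

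The fourth comparison took the cortex. GA20OX2 (AT5G51810), an enzyme of gibberellin synthesis, had the largest margin, at 73.5 against at most 3.08 FPKM. The lipid-transfer protein gene AT2G45180 was at 360.3 against 29.7, the MATE transporter genes AT5G52450 and AT5G65380 at 25.2 and 168 against 1.27 and 15.3, and BGLU11 (AT1G02850) at 31.0 against 2.40 FPKM. Of 6 cortex markers 5 were enriched (median 3.34), including AED3, AT3G05150 at 72.6 FPKM and CVIF2 (AT5G64620), an invertase inhibitor, at 35.8. CO2 (AT1G62500) was highest in endodermis line 2, at 6.97 against 2.39 FPKM in cortex. In limma only 1 of the 6 was called over all genes, AT3G05150, while AED3 and CVIF2 had adjusted p of 0.0938 and 0.176, and 5 were called when adjusted over the list alone. Depleted genes included HSFA6B (AT3G22830), a heat shock factor, at 18.4 against at least 48.1 FPKM, and CCH (AT3G56240), a copper chaperone, at 43.7 against 111. Both had an adjusted p of 0.9999 in limma, and the 9 depleted genes of the cortex compare with 245 in the noise simulation. The RNA-directed DNA methylation, maintenance and heterochromatin medians were -0.28, 0.07 and 0.37, of which the maintenance median was -0.060 with size factors. These lists had 0 limma calls either way, with 0 genes at an unadjusted p under 0.05. Size factors moved the median difference of all genes by -0.12 in cortex. Without endodermis line 1 there were 14 depleted genes, and without line 2 there were 308 enriched and 51 depleted. In limma 101 genes were called, and 0 with size factors, where 564 had an unadjusted p under 0.05.

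The fifth comparison took both endodermis lines against the rest. Genes of the Casparian strip, the lignin barrier of this layer, were far above all other libraries. CASP1 (AT2G36100) was at 2045 FPKM in line 1 and 85.2 in line 2 against at most 8.66, CASP5 (AT5G15290) at 925 and 85.0 against 3.12, and ESB1 (AT2G28670), a dirigent protein, at 1180.4 and 61.8 against 5.57. MYB36 (AT5G57620), which switches on this programme, was at 377 and 70.5 against 3.87. Of 14 endodermis markers 10 were enriched (median 5.58). Among the largest margins were also UCC1 (AT2G32300), a copper protein, at 1809 and 214 FPKM, the peroxidases AT4G11290 at 1253 and 764 and RCI3 (AT1G05260) at 2757 and 1377, and MYB68 (AT5G65790) at 79.1 and 62.3. Of the suberin genes 2 of 5 were measured, and ASFT (AT5G41040) was enriched at 88.2 and 6.48 FPKM. Methylation lists had medians of -0.09 (RNA-directed) and -0.03 (maintenance), which became 0.40 and 0.68 without line 1 and -0.53 and -0.76 without line 2. In limma 12 endodermis markers were called over all genes and 12 adjusted over the list alone, and 0 genes of either methylation list, with 1 and 0 at an unadjusted p under 0.05. The count of enriched genes was 181 without line 1 and 802 without line 2, and of depleted genes 25 and 23. In limma 424 genes were called, and 0 with size factors, where 983 had an unadjusted p under 0.05.

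The 2 endodermis lines differed from each other by a wide margin. Between them 5908 genes, or 43.0% of those at 5 FPKM or more in the higher line, differed at least 2-fold, which ranked ninth among 15 pairs of libraries counted from the fewest. Cortex and endodermis line 2 differed at 1493 genes, endodermis line 2 and stele at 2236, epidermis and endodermis line 1 at 3969, and epidermis and stele at 8848. Across genes the lines correlated with Pearson r 0.841 and Spearman rho 0.836, where genes are not independent replicates, and cortex and line 2 with r 0.944. Line 1 was higher for endodermis markers (median 2.92), xylem markers (2.51), suberin genes (2.36), the stress list (2.0), root cap cell death genes (1.35) and root hair markers (1.31). It was lower for G2 and M phase (-1.66), S phase (-1.59), maintenance (-1.51), RNA-directed DNA methylation (-0.90) and heterochromatin (-1.04). Size factors moved the median difference of all genes between the lines by 0.34. The largest differences toward line 1 were AT1G60750 at 76.4 against 1.02 FPKM, AT3G18280 at 103 against 1.77, AT2G44300 at 73.6 against 1.00, PAL1 (AT2G37040), the entry enzyme of phenylpropanoids, at 469 against 13.0, and AT1G61660 at 46.4 against 0.523. Toward line 2 they were AT4G10955 at 6.48 against 0.113, XTH16 (AT3G23730) at 244 against 38.5, AT3G56220 at 42.0 against 5.82, and the mitochondrial loci ATMG00020 at 427 against 65.4 and ATMG00060 at 15.5 against 1.90.

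**Figure D3:**
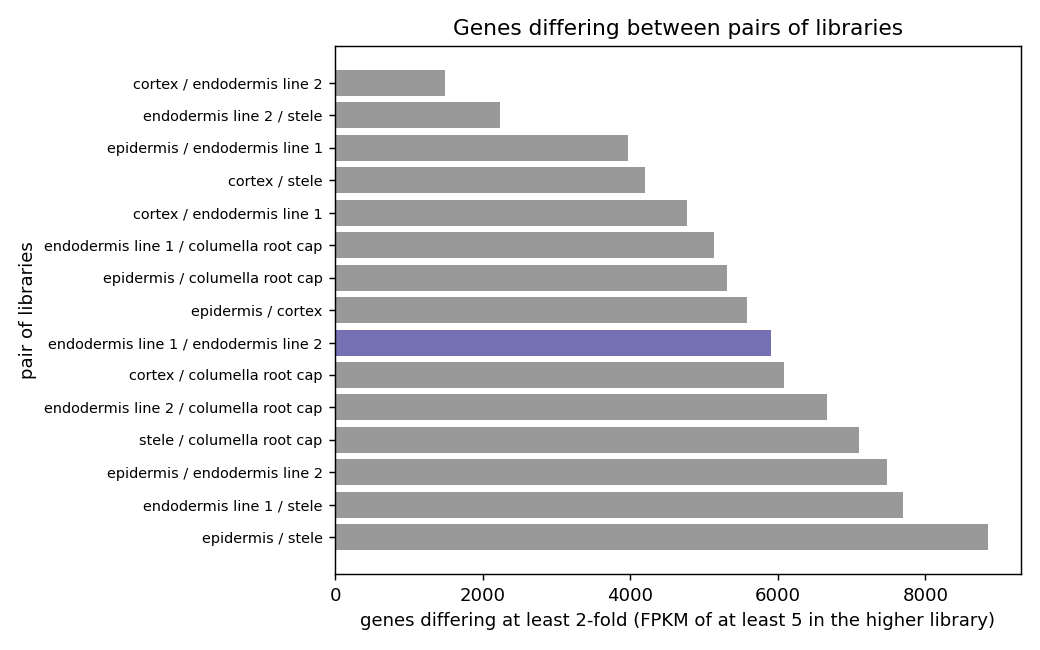
Number of genes differing at least 2-fold (horizontal axis) for each of the 15 pairs of libraries (vertical axis), with the endodermis pair in purple and genes limited to 5 FPKM or more in the higher library. The endodermis lines differ at 5908 genes and cortex and endodermis line 2 at 1493.

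**Figure D4:**
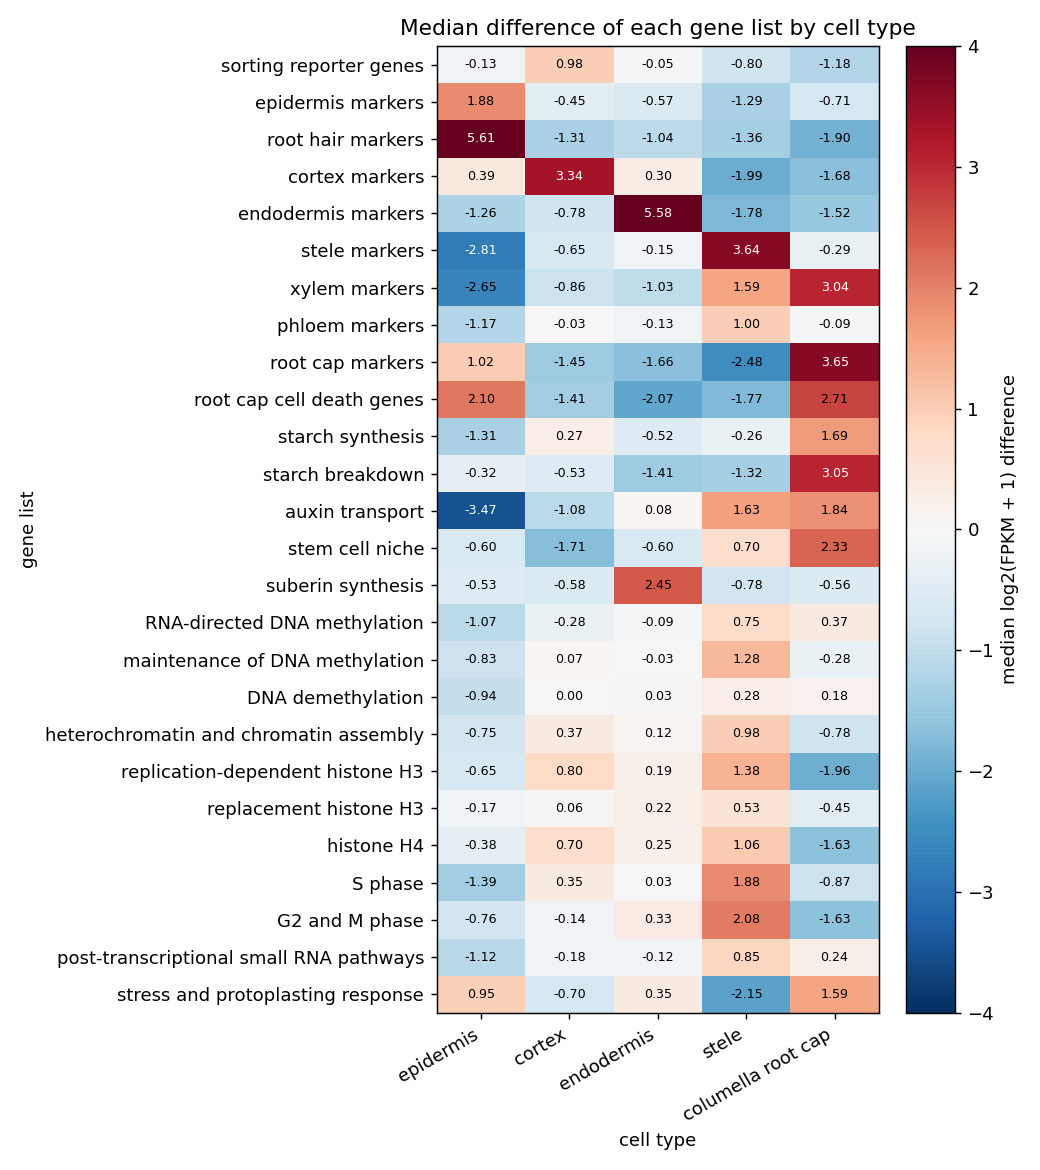
Median difference in log2(FPKM + 1) of each of 26 gene lists (vertical axis) between a cell type (horizontal axis) and the mean of the other 4, with colours ending at -4 and 4. Root hair genes stand at 5.61 in epidermis, endodermis markers at 5.58 in endodermis and root cap markers at 3.65 in columella root cap.

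Loci of the pseudogene class of the reference, which holds 29 of 40 loci whose notes name transposable elements, were little expressed in every library. Of 3911 such loci, 64 reached 1 FPKM in columella root cap, 63 in epidermis, 62 in cortex, 55 and 60 in endodermis lines 1 and 2, and 59 in stele, which is 1.41% to 1.64% of the class. 90 loci reached 1 FPKM in at least 1 library and 3262 were listed at 0 in all 6. A single locus of the class was enriched in columella root cap, SADHU3-2 (AT3G42658), noted as a Sadhu retrotransposon, at 17.7 FPKM against at most 4.44, and it was named after its values were seen. In the other cell types 3 loci of the class were enriched in epidermis, 2 in endodermis, 1 in cortex and 1 in stele. The class does not separate transposable elements from other pseudogenes, and multi-copy elements share reads, so values of single loci are uncertain. Of the 40 noted loci themselves, 17 to 20 reached 1 FPKM in each library. Their summed FPKM was 912 in stele against 649 for the whole class, and 406 against 434 in epidermis. Another 926 loci have the separate biotype of transcribed pseudogene and were left out of the class. The low share of the class is thus no measure of the noted loci. The green tissue list had 0 of 7 members at 1 FPKM in any library.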

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

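No paired analysis was possible because 4 of the 5 cell types have 1 library. Leaving out an endodermis line leaves limma no residual degree of freedom, so it was not run there. Alternatives that leave out the epidermis or columella root cap library, and all those for list medians outside the columella root cap, were chosen after seeing the data. The cause of each move below was not tested, apart from effects of construction. Thresholds by construction admit fewer or more genes. A list high in 1 cell type by construction lowers its medians in the others, which are compared with a mean that includes it. Leaving out epidermis removes that part for root hair and epidermis markers. At 4-fold, enriched and depleted counts were 491 and 32 in epidermis, 40 and 0 in cortex, 96 and 120 in stele, 366 and 27 in columella root cap, 60 enriched in endodermis, and 1318 genes differed between the endodermis lines. Depleted counts of epidermis, cortex and endodermis were 330, 15 and 1 both at 1 FPKM and with no minimum. At 10 FPKM those of epidermis and cortex were 119 and 5. With a pseudocount of 0.1 cortex had 14 and endodermis 1, with TPM 18 and 1. Size factors gave 86 and quantile normalization 125 depleted genes in epidermis, and the latter 1 in endodermis. With the endodermis lines averaged, depleted counts were 322 in epidermis, 27 in cortex, 2 in endodermis and 652 in stele, and enriched counts 283, 316 and 1105 in cortex, endodermis and stele. Leaving out each endodermis line in turn gave 216 to 435 depleted in epidermis, 219 to 308 enriched and 14 to 51 depleted in cortex, 181 to 802 and 23 to 25 in endodermis, and 385 to 1221 and 478 to 685 in stele. Without the columella root cap library epidermis had 1381 enriched and 407 depleted genes and stele 662 depleted. Without epidermis, columella root cap had 436 depleted genes and a heterochromatin median of -1.07. limma made 0 calls in any cell type with size factors, and with no filter on low values 92 in epidermis, 93 in columella root cap and 0 in cortex, endodermis and stele (unadjusted p under 0.05 for 2782, 3108 and 3405). Without the trend it made 343 calls in epidermis, 98 in columella root cap, 21 in endodermis and 0 in cortex and stele (576 and 2071). With a pseudocount of 0.1 cortex had 58 and columella root cap 651 calls, and at 5 FPKM cortex, endodermis and columella root cap had 50, 255 and 582. Pseudogene-class loci at 0.1 FPKM numbered 147 in epidermis and columella root cap, 144 in endodermis line 1 and 134 in cortex, endodermis line 2 and stele, and at 5 FPKM 27, 28, 23, 27, 29 and 32 in that order. Over all settings 56 values of list medians changed sign. Of these, 49 belong to medians inside the interval of random lists, such as epidermis markers in cortex without epidermis (1.31, from -0.45), or in endodermis without line 2 S phase (-0.77, from 0.03) and replication-dependent H3 (-0.63, from 0.19). The other 7, of medians outside that interval, are called reversed. They were, in endodermis, xylem markers (0.093) and G2 and M phase (-0.48) without line 2, against -2.15 and 1.2 without line 1, and stress (-0.41) without line 1, against 1.34 without line 2, and, without epidermis, root hair markers in cortex (0.11), endodermis (0.41) and stele (0.081) and epidermis markers in endodermis (0.14). Of the values not called reversed for named genes and for list medians, leaving aside the 4 methylation and chromatin medians of the columella root cap, 2626 moved by less than the spread between the endodermis lines and 306 by more. For named genes the filters on low values could not move a value. The 174 values with no filter and the 174 at 5 FPKM are thus among the 2626 by construction. Depth limits low genes most, and the reads behind them are unknown.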

Other observations

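Gene families, taken from the reference products after the data were seen, were tested for enrichment among the enriched genes of each cell type with a one-sided Fisher's exact test over genes that reached 5 FPKM, with 614 tests adjusted by Benjamini-Hochberg. Genes are not replicates, so these tests describe single libraries. In endodermis 8 of 14 peroxidase genes (adjusted p = 3.51e-10), 6 of 11 dirigent-like genes (2.18e-07) and 7 of 21 arabinogalactan protein genes (5.11e-07) were enriched, against 1.29% of all genes. In epidermis 27 of 38 genes with a cysteine and histidine-rich C1 domain (1.64e-19), 13 of 13 root hair specific genes (8.75e-13), 16 of 32 WRKY factors (3.49e-08) and 8 of 13 xyloglucan endotransglucosylases (6.38e-05) were enriched, against 7.65%. Peroxidase genes passed in epidermis as well, with 12 of 23 enriched (2.02e-06). WRKY factors respond to wounding and stress, and the stress list also had a positive median in epidermis (0.95). That list itself holds WRKY33 and WRKY40, so it is no separate evidence. Of its 11 measured members 0 were enriched in epidermis and 1 lay above the range of the other libraries with a log2 difference of at least 1. In cortex 5 of 12 MATE transporters (2.23e-05) were enriched, in stele 8 of 46 leucine-rich repeat kinases (0.000925) and 4 of 15 GATA factors (0.0175), and in columella root cap 6 of 15 exostosin family genes (0.0281).

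Of the tests below, those of distance from the S phase lines and of the scaling of RNA-directed DNA methylation genes were set before their results were seen, and the others were chosen after. In the columella root cap library 4 RNA-directed DNA methylation genes were enriched while heterochromatin genes were low (median -0.78). The heterochromatin median was nearly as low in epidermis (-0.75, 6.1 percentile). There, however, it lay inside the interval of random lists (-0.82 to 0.39). The median of all measured genes was also lower in epidermis, at -0.39 against -0.048 in columella root cap. Whether the low heterochromatin median is particular to the columella root cap library thus stays open. The pattern did not depend on the choice among the scalings tried: the same 4 genes stayed enriched under size factors, TPM and quantile normalization, and the highest heterochromatin median under these was -0.76. These scalings moved the median difference of all genes in this library by only 0.0025, 0.096 and -0.12 in that order. Such small moves could hardly have changed the result, so larger errors of scaling were not tested. More cells in S phase are argued against for the RNA-directed genes, as the S phase list was itself low (median -0.87). Columella root cap lay 1.04 above a line on the S phase mean fitted on the other 5 libraries, against at most 0.30 for any of these. This went beyond the limit set in the prediction, but it rests on 1 library, so no conclusion is drawn from it. Over all 6 libraries, columella root cap included, these genes followed the S phase mean loosely (Pearson r = 0.662, exact permutation p = 0.131, adjusted 0.131 over 7 relations, Spearman rho = 0.829, exact p = 0.0583, adjusted 0.0817, r = 0.20 without epidermis and stele). The heterochromatin list mean followed the S phase list mean over the 6 libraries (Pearson r = 0.983, exact permutation p = 0.00556, adjusted 0.0292 over 7 relations; Spearman rho = 0.943, exact p = 0.0167, adjusted 0.0583; r = 0.984 without epidermis and stele). Columella root cap lay -0.21 from a line fitted on the other 5 libraries, against at most 0.12 for any of these. By the prediction this would argue against fewer cells in S phase. However, replication-dependent H3 and H4 genes lay -1.19 and -1.07 from their own lines, and the S phase list holds the enriched RNR2A. The S phase mean may thus understate the loss of dividing cells. This use of H3 and H4 genes was not part of the prediction, and the split of reads between histone copies is uncertain. A loss of dividing cells cannot be told apart from a difference of cell type with 1 library.

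Xylem markers were higher in the columella root cap than in the stele library. The values argue against stele cells as sorted, since their share could not lift a gene above its stele level: the median xylem marker was 2.8-fold higher in columella root cap (FPKM + 1), while the median stele marker was at 0.227-fold and the highest at 1.96-fold. Xylem cells alone, carried into the sort, may be a source, as 7 of 8 xylem markers were higher in columella root cap than in stele, VND7 being the exception. This cannot be told apart from expression in the sorted cells, since no library of xylem cells was used here. Of the stele-enriched genes outside the list, the xylem factor XND1 was at 1.29 FPKM in columella root cap against 32.9 in stele. NAC105 was at 2.23 against 47.0, LAC6 at 1.56 against 52.0 and ACL5 at 7.14 against 194. By the rule of size, stele-enriched genes always lie lower in columella root cap, so these values decide nothing about carried xylem cells.

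The endodermis lines differed at more genes than endodermis line 2 and cortex. Scaling does not account for it: the first count was at least 3.32 times the second under size factors and quantile normalization. Of 2736 genes higher in line 1, 676 (24.7%) were at least 2-fold above every other library, where a mixture cannot reach apart from measurement error. Simulated noise as wide as the difference between the lines put 365 to 410 genes of a single-library cell type that far above all others. The count of 676 exceeds this, so for part of these genes the values argue against cells of the other sorted types in line 1. Which of the 676 these are cannot be told. Of the other 2060 genes, 1398 lay inside the range of the other libraries and 662 above it by less than 2-fold. For these a mixture cannot be told apart from a change in the endodermis cells. Both can put a gene inside the range, and no replicate of line 1 gives the error of so small a margin above it. The 676 genes do not bear on cells of other types in line 2, which were not tested. Line 2 differed least from cortex (1493 genes) and stele (2236). The medians of cortex and stele markers between the lines were small (0.07 and 0.08, line 1 minus line 2), but their members went both ways. Of 6 cortex markers 2 were at least 2-fold higher in line 1 and 2 at least 2-fold lower. Of 12 stele markers 3 were higher and 1 lower by as much. These lists thus do not decide whether line 2 held cortex or stele cells. More differentiated cells in line 1 are a candidate explanation, with a G2 and M phase median of -1.66 and an endodermis marker median of 2.92. The stress list median of 2.0 leaves a response to cell isolation open beside it, and xylem (2.51), root hair (1.31) and root cap cell death (1.35) medians leave cells of other types open.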
